A study of Caenorhabditis elegans with 2 samples.

How the data were processed

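The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of HLH-12, a basic helix-loop-helix transcription factor of Caenorhabditis elegans, from whole hermaphrodite young adults collected 64 hours after synchronization. Per the labels, the worms were of strain OP538, a transgenic line in an unc-119 mutant background that expresses HLH-12 with a C-terminal GFP tag, and the protein was precipitated with an antibody against GFP after sonication. The labels give 2 biological replicates in 1 group, so p-values here concern positions, sequences and genes in the peak lists and no test compares groups of animals.

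The authors deposited a relaxed peak list for each replicate and a relaxed list called on both replicates together. They also deposited a list thresholded by the irreproducible discovery rate (IDR), a measure of how alike peaks rank in repeated lists. Presence in the IDR list does not by itself show that a peak ranked alike in both replicates. Each list was deposited for the genome builds ce11 and ce10. Per the file listings among the deposited files, the relaxed lists were called with a control, while the aligner, the peak caller and the treatment of reads that match several places are not given in the sources used here. Signal tracks, alignments and the control library were not analysed here. The signal value of each peak was deposited by the authors as the peak caller wrote it, and whether it was scaled for sequencing depth is not given in the sources used here. The −log10 q value of each peak was likewise deposited by the authors, and the p-value column held no values. Read depth per sample is unknown, so intervals on shares are 95% Wilson intervals that cover the sampling of peaks only. In ce11, the list of replicate 1 held 19792 peaks, that of replicate 2 held 22570, the pooled relaxed list 6676 and the IDR list 245. Nearly all peaks had a fixed width, 436 bp in 95.9% of the IDR list. The IDR list was the 245 pooled peaks of highest signal. The pooled signal was close to the sum of the replicate signals, with a median ratio of 1.00.

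Positions were taken from the ce11 lists and compared with the WBcel235 reference genome and its Ensembl 115 annotation, whose chromosome lengths hold every ce11 peak. tRNA isotypes came from the RefSeq annotation of the same assembly through shared gene identifiers, which matched 607 of the 612 nuclear tRNA genes. The ce10 lists entered only the comparisons that need no annotation, with ce11 chromosome lengths, after removal of 1 malformed peak wider than 10000 bp. Tests used the 230 IDR peaks on the 6 nuclear chromosomes. The design had not foreseen the 15 mitochondrial IDR peaks, for which no matched control windows exist, so they are given separately.

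A promoter ran from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene. Shares of summits in promoters or within 200 bp of a tRNA, snoRNA, snRNA, rRNA or microRNA gene (small RNA genes below) were compared with 10000 random placements that kept the number of peaks per chromosome. The smallest two-sided p these can give is 0.0002. Chromosome shares were compared with chromosome length by an exact binomial test. E-boxes (CANNTG, the sequence that basic helix-loop-helix factors bind) and all 2080 6-mers, each with its reverse complement, were searched within 50 bp of each summit. Control windows were matched for chromosome, promoter class and GC fraction within 0.05 and lay at least 1000 bp from pooled peaks, with 100 per summit. E-boxes were tested by resampling these windows and 6-mers by Fisher's exact test. Gene lists were compared with all 19865 protein-coding gene names on the nuclear chromosomes by Fisher's exact test. Annotation classes of summits used protein-coding genes alone, so intergenic means outside their transcripts, and were compared with 1000 placements. All tests were two-sided, and families of tests were adjusted by Benjamini-Hochberg at 0.05. Replicate support was the share of IDR peaks overlapping, by at least 1 bp, the 230 strongest nuclear peaks of each replicate list. The replicate signal of a peak was the highest signal among overlapping peaks of that replicate, and the rank correlation had 100000 permutations.

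The tests, the 22 gene lists and the rule for named genes were fixed before the data were examined. Named are the genes whose promoter holds one of the 20 strongest summits, or else the gene with the nearest 5′ end; every member of the distal tip cell list; hlh-12 and unc-119; and up to 4 members of each other list with the strongest promoter peak. The alternatives were the ce10 lists, other promoter and motif windows, other distances and backgrounds, stricter overlap, the 115 stronger peaks, removal of neighbouring summits or of peaks within 20000 bp of hlh-12 or unc-119, and each replicate alone through its 230 strongest nuclear peaks. Inclusion of the mitochondrial peaks, removal of peaks at small RNA genes, the direct comparison of the replicate lists and the comparison within autosomes were chosen after seeing the data.

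The code was tested on simulated data. With summits moved onto small RNA genes for 40% of 230 peaks, the recovered share was 40.4%. With CAGCTG planted at 10% of 230 summits, the class was called in 20 of 20 sets, while the share with any E-box was called in 8 of 20. With 20% planted, both were called in 20 of 20 sets, and with none planted in 0 of 20. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.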

Results

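HLH-12 is a basic helix-loop-helix protein known for its part in the migration of the distal tip cells, which lead the growing arms of the gonad. Its genomic positions in whole young adult worms were read from ChIP-seq peak lists of 2 biological replicates of 1 transgenic strain. Per replicate, the relaxed lists held 21181 ± 1964 peaks (SD, n = 2). The IDR list, made by the authors from both replicates, held 245 peaks in ce11, of which 230 lay on the nuclear chromosomes and 15 on the mitochondrial genome. Their −log10 q lay between 1.04 and 1.13. All coordinates are ce11 and count from 1. Signals are the authors' peak values. A signal given with its SD is the mean of both replicate lists, and the pooled signal, which sets the ranks, is close to their sum. No library from animals without the tagged protein was analysed here.

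The first question was how far both replicates gave the same peaks. The nuclear peak of highest pooled signal (245.4), in an intron on chromosome V (8500494 to 8500670) at the snoRNA gene ZK994.7, had a replicate signal of 119.3 ± 29.3 (SD, n = 2). Its nearest protein-coding 5′ end was that of pxn-1, a peroxidasin gene, 5665 bp away. Of the 230 nuclear IDR peaks, 107 (46.5%, 95% Wilson interval 40.2 to 53.0) overlapped the 230 strongest peaks of both replicates. IDR peaks were picked by pooled signal, so an overlap above the 0.116% of random placement is set by that selection. Compared directly, without the IDR list, 46.5% of the 230 strongest peaks of replicate 1 overlapped the 230 strongest of replicate 2, against 0.237% under random placement (permutation p = 0.0002, the smallest possible), a comparison chosen after the data were seen. Of the IDR peaks, 75.2% overlapped the 230 strongest of replicate 1 and 64.3% those of replicate 2. In the whole relaxed lists, 99.6% had a counterpart in both. Signal was higher in replicate 1 at 181 of the 229 peaks with a value in both.

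The order of the peaks by signal was shared in part. Across the 229 peaks, the rank correlation of the 2 replicates was 0.15 (permutation test, p = 0.0233), and Pearson's r of log2 signal was 0.33 (permutation p = 1e-05, the smallest possible). Peaks are not independent replicates, and overlapping IDR peaks can carry the same replicate values. Those at V 265217 to 265652 and 265548 to 265983 both carry 149.8 in replicate 1 and 110.8 in replicate 2. These are the highest nuclear signals of each list, so the most extreme point is counted more than once. The median SD between replicates was 9.07, against an SD of 14.9 among the peak means. The median ratio of replicate 1 to replicate 2 signal was 1.38, so each SD between replicates also carries this offset. The IDR peaks were those of highest pooled signal, close to the sum of both replicates, and this selection affects the correlation. Without the peaks at small RNA genes, the correlation was -0.16 over 59 peaks (p = 0.237).

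**Figure D1:**
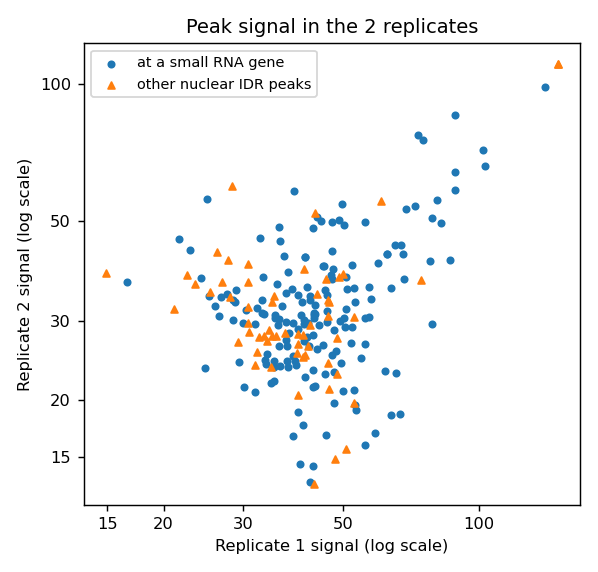
Signal of each nuclear IDR peak in replicate 1 (x axis) and replicate 2 (y axis), in the authors' signal units on log scales; points are the 229 peaks with a value in both. Most points lie toward replicate 1, which was higher at 181 peaks, and the strongest peaks stand out in both.

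The next question was which annotated features lie under the peaks. Most nuclear peaks lay at genes of small noncoding RNAs. Of 230 summits, 171 (74.3%, 68.3 to 79.6) were within 200 bp of such a gene, against 0.712% under random placement and 3.91% in the highest of 10000 placements (permutation p = 0.0002, the smallest possible). tRNA genes accounted for 124 summits (53.9%), snoRNA genes, whose products guide RNA modification, for 35 (15.2%) and snRNA genes for 10 (4.35%), each with an adjusted permutation p of 0.000333. MicroRNA genes had 2 summits (0.870%, against 0.132% under placement, adjusted permutation p = 0.0932). rRNA genes had 0 of 230 (upper Wilson bound 1.64%). Seen from the genes, 133 of 612 nuclear tRNA genes (21.7%), 36 of 346 snoRNA genes (10.4%), 9.30% of the snRNA genes and 2 of 261 microRNA genes (0.766%) held an IDR summit within 200 bp.

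Of the 20 strongest nuclear peaks, 10 lay at snoRNA genes, 7 at tRNA genes and 1 at an snRNA gene. Here snoRNA genes led, where tRNA genes led among all 230, and this difference was not tested. Besides ZK994.7, the snoRNA gene T06C12.16 on V (15873761 to 15874196, intergenic, nearest 5′ end str-56, a chemoreceptor gene) had a signal of 84.7 ± 26.5 (SD, n = 2). On chromosome I (8259354 to 8259789, intergenic), ZK265.10 lay in the promoter of sre-23, also a chemoreceptor gene, with 87.0 ± 2.14 (SD, n = 2). The snRNA gene R07E5.16 on III (10989518 to 10989953, intron, nearest 5′ end col-94) had 75.3 ± 0.0526 (SD, n = 2). A pair of alanine tRNA genes on X (9743470 to 9743905, intron, nearest 5′ end F15G9.5) had 75.2 ± 2.88 (SD, n = 2). Another alanine tRNA gene on X (6292094 to 6292529, intergenic) lay in the promoters of lev-9 and mom-1, with 63.1 ± 13.1 (SD, n = 2). The snoRNA gene F38E11.14 on IV lay in the promoter of wrt-3, a hedgehog-related gene, with 66.0 ± 23.6 (SD, n = 2).

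For 11 further peaks among these 20 the nearest protein-coding 5′ ends were those of F55C5.17, W03C9.1, pamn-1, cutl-18, srd-43, M02F4.2, ppat-1, sulp-3, col-181, lact-7 and K07H8.7, and each had a small RNA gene at the summit. The remaining 2 had none. One lay between genes on V (265217 to 265652), 2872 bp from the 5′ end of lgc-26. Its pooled signal was 236.4 and its replicate signal 130.3 ± 27.6 (SD, n = 2), first in rank among the nuclear peaks of each replicate list. The other lay on I (11374232 to 11374667), in the promoters of wbp-4 and F56G4.6, with 58.1 ± 3.91 (SD, n = 2).

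The share at small RNA genes fell with signal rank through the pooled relaxed list. It was 84.3% in the first 115 nuclear peaks, 64.3% in the next 115, 39.3% at ranks 231 to 500 and 2.29% at ranks 4001 to 6661. Against the 6388 lower-ranked peaks, of which 5.40% lay at small RNA genes, the IDR peaks had an odds ratio of 50.8 (Fisher's exact test, p = 7.37e-149). This comparison with lower-ranked peaks was chosen after the data were seen.

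**Figure D2:**
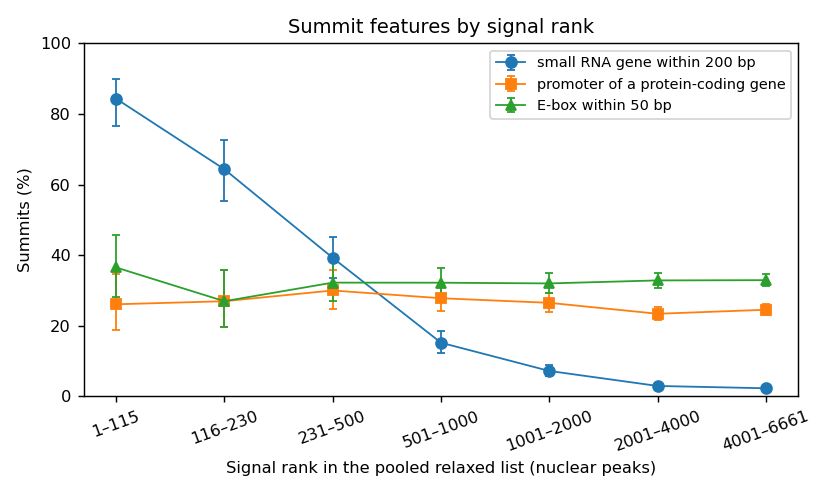
Share of summits (y axis, percent, with 95% Wilson intervals) at a small RNA gene, in a promoter or with an E-box, by signal rank in the pooled relaxed list (x axis). The small RNA share falls from 84.3% to 2.29% while the promoter and E-box shares stay between 23.4% and 36.5%.

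Protein-coding promoters held 61 of the 230 summits (26.5%, 21.2 to 32.6), against 20.5% under random placement (permutation p = 0.0308). The median distance to the nearest protein-coding 5′ end was 1300 bp, against 1696 bp under placement (permutation p = 0.0048). To the nearest 5′ end of any gene, coding or not, the median was 37 bp against 1023.5 bp (permutation p = 0.0002). Over the 59 peaks away from small RNA genes, the median distance to a protein-coding 5′ end was 1145 bp against 1604 bp, not past the threshold (permutation p = 0.0922). By annotation of protein-coding genes alone, 121 summits (52.6%) were intergenic against 39.0% under placement (adjusted permutation p = 0.00599). In introns were 93 (40.4%) against 32.6% (adjusted permutation p = 0.0519), and in coding exons 10 (4.35%) against 23.5% (adjusted permutation p = 0.00599). Only 35 of the 121 intergenic and 15 of the 93 intronic summits lay away from small RNA genes. These shares therefore largely describe where the small RNA genes lie. The promoter share was past the threshold too with promoters of 2000 bp upstream and 500 bp downstream (46.96% against 38.4%, permutation p = 0.0094) and among the 59 peaks away from small RNA genes (33.9% against 21.7%, permutation p = 0.0394). It was not past the threshold with promoters of 500 bp upstream (16.1% against 12.5%, permutation p = 0.125), nor among the 115 stronger peaks (26.1% against 20.3%, p = 0.154).

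Promoter share did not separate strong from weak peaks. It was 26.1% in the 115 stronger and 26.96% in the 115 weaker IDR peaks (Fisher's exact test, p = 1), and 26.5% in IDR peaks against 24.9% in lower-ranked peaks (p = 0.587).

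By chromosome, X carried 82 of the 230 peaks (35.7%, 29.7 to 42.03) with 17.7% of the nuclear genome's length, a 2.02-fold excess (exact binomial test, adjusted p = 5.78e-10 over 6 chromosomes). Against the whole nuclear genome, chromosome V (32 peaks, 0.667-fold) and chromosome I (22 peaks, 0.636-fold) were lower, but an excess on X lowers every other share. Among the 148 autosomal peaks, V was at 0.853-fold and I at 0.814-fold of their share of autosomal length, and none of the 5 autosomes differed by the exact binomial test, with adjusted p from 0.552 to 0.916. Of the tRNA genes, 45.1% lie on X. Among the 59 peaks away from small RNA genes, 7 were on X (11.9%, 5.87 to 22.5).

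**Figure D3:**
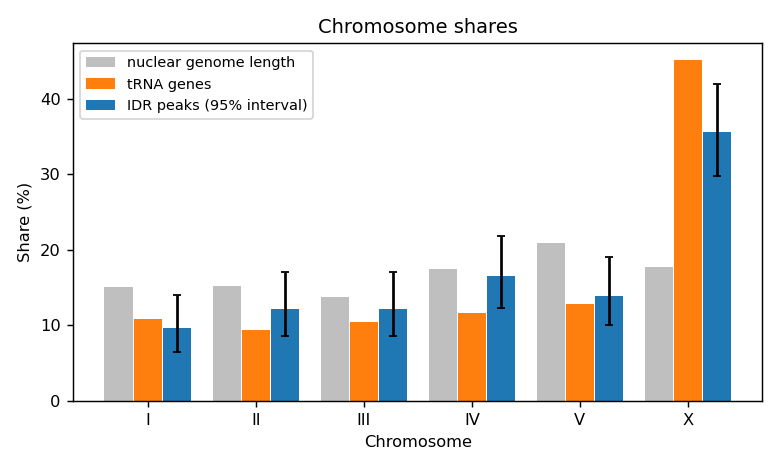
Share of nuclear genome length, of nuclear tRNA genes and of nuclear IDR peaks on each chromosome (y axis, percent; error bars are 95% Wilson intervals of the peak share). X has 17.7% of the length, 45.1% of the tRNA genes and 35.7% of the peaks.

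The recognition sequence of the factor's family was then searched at the summits. An E-box was present within 50 bp of 73 of 230 summits (31.7%, 26.1 to 38.01), against 37.4% in matched control windows (permutation test, p = 0.0794). With replicate 2 left out it was 30.4% against 37.2%, lower past the threshold (permutation test, p = 0.0378), and with replicate 1 left out 35.2% (p = 0.595). Of the 10 E-box classes, CACATG was higher, at 23 summits (10.0%, 6.76 to 14.6) against 3.71% (adjusted permutation p = 0.002), and the other 9 were not past the threshold. CAGCTG occurred at 3 summits (1.30%) against 3.21% (adjusted permutation p = 0.296), and CACCTG at 5 (2.17%) against 3.93% (adjusted p = 0.423). CACATG was also called within 100 bp (15.2% against 7.44%), among the 115 stronger peaks (11.3% against 3.83%) and from replicate 2 alone (9.57% against 3.84%). It missed the threshold after adjustment within 25 bp (5.22% against 1.95%, adjusted permutation p = 0.066), against windows 500 bp to each side (10.0% against 4.35%, Fisher's exact test, adjusted p = 0.0676) and from replicate 1 alone (7.39% against 3.96%, adjusted permutation p = 0.196). Without the peaks at small RNA genes it occurred at 5 of 59 summits (8.47% against 3.49%, permutation p = 0.109, adjusted p = 0.544).

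**Figure D4:**
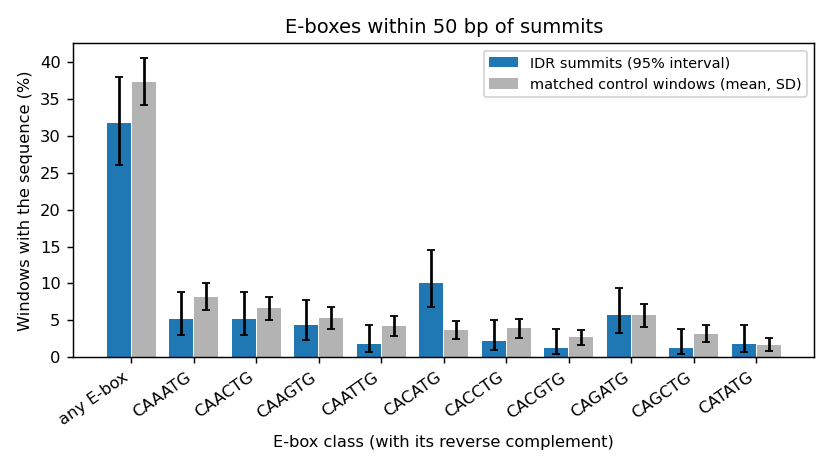
Share of windows (y axis, percent) with any E-box or each of the 10 E-box classes (x axis) at the 230 IDR summits, with 95% Wilson intervals, and in matched control windows, with the SD over resampled sets. CACATG is at 10.0% against 3.71%, and any E-box at 31.7% against 37.4%.

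E-box presence showed no call by signal. It was 36.5% in the 115 stronger and 26.96% in the 115 weaker peaks (Fisher's exact test, p = 0.156). With windows of 100 bp on either side, the difference was 20 percentage points and passed the threshold (Fisher's exact test, p = 0.00349). IDR peaks had an E-box at 31.7% and lower-ranked peaks at 32.7% (Fisher's exact test, p = 0.830).

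Among all 6-mers, 188 were more frequent at the summits than in control windows and 74 were less frequent. The more frequent ones numbered 102 with replicate 1 left out, 176 with replicate 2 left out and 84 within 25 bp. The leading ones were GTTCGA, at 33.0% of summits against 4.33%, CGAACC at 28.7% against 3.10%, GAACCC at 22.6% against 3.33% and ACCACT at 21.7% against 4.62%, with adjusted p from 7.56e-41 to 5.98e-17 by Fisher's exact test. The summit windows are not independent sequences: 116 of the 133 tRNA genes with a summit have identical copies. GTTCGA is the core of the B box, the internal promoter element of tRNA genes. Over the 59 summits away from small RNA genes, Fisher's exact test called 0 6-mers after adjustment, with 105 at an unadjusted p under 0.05.

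The last question was which kinds of protein-coding genes had a peak in their promoter. There were 73 such genes among 19865, and the distal tip cell genes were not among them. All 29 members lacked an IDR peak: the factor genes hlh-12, hlh-2, ceh-22, vab-3, lin-29, daf-12, blmp-1, pop-1, sys-1 and lin-42, the Notch ligand genes lag-2 and apx-1, the matrix and integrin genes gon-1, mig-17, mig-6, fbl-1, ina-1, pat-2 and pat-3, the guidance genes unc-5, unc-6, unc-40 and unc-129, and dre-1, ced-10, mig-2, ced-5, ced-2 and ced-12. The nearest IDR summit to any of their 5′ ends was 13.5 kb away, at unc-6, and the median was 315.9 kb. These distances were not compared with those of other genes. With 0.107 members expected by chance to have an IDR promoter peak, the absence of all 29 does not show a depletion. In the pooled relaxed list, 3 of the 29 (10.3%) had a promoter peak, against 9.08% of all genes (Fisher's exact test, p = 0.744): ced-5 with a pooled signal of 43.9, mig-2 with 38.7 and ced-12 with 27.8. The lowest pooled signal of a nuclear IDR peak was 57.3.

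Of the 22 gene lists, 0 were enriched or depleted by Fisher's exact test after adjustment, and 0 had an unadjusted p under 0.05. Under the alternatives 0 passed after adjustment, and 3 tests had an unadjusted p under 0.05. With the nearest gene at any distance these were chemoreceptors (5 genes against 13.9 expected, Fisher's exact test, unadjusted p = 0.011) and cuticle collagens (5 against 1.91, unadjusted p = 0.0435). From replicate 2 alone it was ribosomal proteins, with 2 genes against 0.314 expected (Fisher's exact test, unadjusted p = 0.0395). In the main assignment, 5 lists had any member with a promoter peak. The values that follow are replicate means. Among 79 ribosomal protein genes it was rpl-3 (III, 3867359 to 3867794, signal 33.2 ± 24.9, SD, n = 2). Among 38 mitochondrial respiration genes it was cox-6A (42.6 ± 4.12, SD, n = 2), beside an snRNA gene. Of 176 cuticle collagen genes it was col-185 (37.0 ± 22.5, SD, n = 2), and of 188 detoxification genes cyp-43A1 (30.1 ± 8.87, SD, n = 2), each beside a tRNA gene. Of 1276 chemoreceptor genes, sre-23 and srh-269 had one (87.0 ± 2.14 and 29.8 ± 7.56, SD, n = 2), where 4.69 were expected by chance. The other 17 lists, of 11 to 274 genes, had none: distal tip cell, basic helix-loop-helix factors, histones, intestine, sperm, germline and oocyte, muscle, pharynx, neuropeptides, pan-neuronal and synaptic, homeobox, nuclear receptors, basement membrane and adhesion, Wnt and Notch, heterochronic, heat shock, and proteasome. With at most 1.01 genes expected per such list, a depletion was not detectable.

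The loci carried by the transgene had no IDR peak within 20000 bp. At hlh-12 (IV, 8478595 to 8479446), the pooled relaxed list had 4 peaks within that distance against 2.71 expected from the genome-wide density, the strongest with a pooled signal of 51.2. At unc-119 (III, 10902641 to 10908935), it had 2 against 3.08, the strongest with a pooled signal of 28.8.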

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

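The tests of transcription class (tRNA and SL2 RNA genes against microRNA genes, and 5S rRNA and SL1 RNA against tRNA genes), the E-box test at small RNA genes and the tests on the X chromosome, including its split by tRNA copies and the comparison with chromosome IV, were chosen only after the results were seen.

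A signal outside the main measurement was present on the mitochondrial genome, which held 15 of the 245 IDR peaks. These are 6.12% of the peaks and 49.6% of the summed signal, over a genome of 13794 bp. The list of replicate 1 held 10 mitochondrial peaks and that of replicate 2 held 14. The IDR peak second in signal, at 12137 to 12638, overlapped no peak of replicate 1, nor did those at 10754 to 10904, 10141 to 10249 and 9101 to 9209. Their pooled signals (3891, 718.3, 505.9 and 357.5) were above their replicate 2 signals (1597, 277.2, 81.3 and 72.1). Absence from the list of replicate 1 therefore does not show that it lacked signal there. The 15 are not all separate: 4462 to 5105 is listed with summits at 4675 and 4952, and 2815 to 3250 overlaps 3085 to 3520. Their median pooled signal was 718.3 against 70.9 for nuclear peaks. The strongest, at 4462 to 5105 in the gene WBGene00000829, had a replicate signal of 2377 in replicate 1 and 1810 in replicate 2. Others lay in COX3 (5788 to 6223) and ND1 (2131 to 2270), components of the respiratory chain. By pooled signal, 2 nuclear peaks (245.4 and 236.4) were stronger than the weakest mitochondrial one (197.8). No control level was analysed here.

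The concentration of peaks at small RNA genes was weighed against 3 technical explanations and against binding at E-boxes. The tests of identical copies and of RNA polymerase III genes left out snoRNA genes, which had 35 of the 171 summits. GC content does not account for it, since GC-matched placements reached at most 5.22% at small RNA genes against 74.3% observed. An E-box was present at 30.4% of the 171 summits, against 38.7% in control windows (permutation p = 0.0298, lower). The control windows were not taken at small RNA genes, whose own sequence affects this share, so the comparison cannot decide on binding at E-boxes. Reads shared between identical tRNA copies may contribute, and whether such reads were kept is not given in the sources used here: single-copy tRNA genes held a summit 0.494 times as often as those with identical copies (17 of 140 against 116 of 472, Fisher's exact test, p = 0.00153), just past the bound of 0.5 set for this explanation, with an interval of 0.308 to 0.793 that spans it, and 12.1% of single-copy genes still held one. Signal that follows RNA polymerase III genes, whether through HLH-12 or a background of the precipitation, may account for the tRNA part. tRNA genes held a summit more often than microRNA genes with an odds ratio of 36.0 (Fisher's exact test, p = 4.06e-20). This contrast was already known when the test was chosen, so the test adds no support. Summits also lay in rpr-1, mrpr-1 and srpr-2.2, other genes of RNA polymerase III, which were singled out because they held one. The 16 annotated 5S rRNA genes, also transcribed by RNA polymerase III, held 0 (against 21.7% of tRNA genes, Fisher's exact test, p = 0.0302), and whether reads map uniquely there was not tested. If signal followed RNA polymerase III genes alone, SL2 RNA genes, transcribed by RNA polymerase II, would hold summits no more often than microRNA genes. Of SL2 RNA genes, 4 of 18 held one (22.2%), with an odds ratio of 37 against microRNA genes (Fisher's exact test, p = 0.000171). The group was picked after its summits were seen, so this test cannot decide on the explanation. SL1 RNA genes, also transcribed by RNA polymerase II, held 0 of 12 (upper Wilson bound 24.2%, Fisher's exact test, p = 0.0797 against tRNA genes). The tests on 5S rRNA and SL1 RNA genes count each gene as independent, and identical or neighbouring copies would make their p-values too small. Whether reads map uniquely at SL1 RNA genes was not tested, nor was a role of HLH-12 at the small RNA genes.

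The excess on X lay with the peaks at small RNA genes: 43.9% of those were on X, against 11.9% of the 59 other peaks (17.7% by length, exact binomial test, p = 0.306, interval 5.87 to 22.5). The number of tRNA genes on X, 45.1% of all, may account for part of this excess. It left a remainder, since those genes held a summit more often than autosomal ones (29.0% of 276 against 15.8% of 336, odds ratio 2.18, Fisher's exact test, p = 0.000112). The tests on tRNA genes count genes that share a summit, and identical copies, as independent. Among the autosomes the shares were 10.9% to 14.1% on I, II, III and V and 26.8% of 71 (17.9 to 38.1) on IV, and the test of X against IV, picked for its high share, left open whether these differ (odds ratio 1.12, Fisher's exact test, p = 0.770). Among tRNA genes with identical copies the shares were 32.1% and 17.9% (Fisher's exact test, p = 0.000397), and among single-copy genes 16.4% and 9.41% (p = 0.290). Whether X-linked tRNA genes may differ for a biological reason was not tested.

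The CACATG excess may reflect the sequence around tRNA genes: 18.05% of tRNA genes with a summit and 12.5% of those without had CACATG within 50 bp (odds ratio 1.54, Fisher's exact test, p = 0.117), which does not show that the shares are equal. Of 25 CACATG sites at the summits, 7 (28.0%, 14.3 to 47.6) lay inside a small RNA gene, so gene sequence was not the place of most sites. With 59 summits away from small RNA genes (8.47% against 3.49%, permutation p = 0.109), these data left open whether the excess exists there, and binding of HLH-12 to CACATG was not tested.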

How the results depend on the processing

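The settings that include mitochondrial peaks, remove peaks at small RNA genes or compare the replicate lists directly, and the ranks by single replicate, were chosen after the data were seen. Removing neighbouring summits or peaks near hlh-12 and unc-119 took out 0 IDR peaks, and the 15 alternatives to the main results that could not change for this reason test nothing. Of the 84 others, 63 kept direction and side of the threshold, or a count within 1.5 times, and 7 changed direction. The 63 include replicate support of IDR peaks, set by their selection, and counts of 0 enriched gene lists, where few genes were expected. Those add little on robustness. Besides the X share and the signal correlation, the 7 that changed direction were differences in percentage points that passed the threshold in neither setting: promoter share of stronger minus weaker peaks (-0.87 in the main setting, -8.70 to 5.22 with either replicate left out), promoter share of IDR minus lower-ranked peaks (1.63, and -0.49 at 500 bp upstream), and E-box share of IDR minus lower-ranked peaks (-0.92, and 0.52 within 25 bp, 1.28 within 100 bp and 2.94 without peaks at small RNA genes). The small RNA share lay between 39.6% (summit inside the gene) and 84.3% (115 stronger peaks) and was 60.9% and 75.7% from replicate 2 and replicate 1 alone. Promoter share lost its call at 500 bp upstream (16.1%), in the 115 stronger peaks (26.1%, where the number of peaks was smaller) and against lower-ranked peaks (26.5% against 24.9%), and kept it at 2000 bp (46.96%), from either replicate alone (26.1% to 28.7%) and away from small RNA genes (33.9%). Without peaks at small RNA genes, which left 59, the X share was 11.9%, the signal correlation -0.16, the median 5′ distance 1145 bp against 1604 bp under placement (permutation p = 0.0922, with fewer peaks), and 0 E-box classes and 0 6-mers were called. With the mitochondrial peaks the signal correlation was 0.26. The E-box share ranged from 30.4% to 35.2% with either replicate left out, and passed the threshold, as lower than controls, without replicate 2 (permutation p = 0.0378). E-box classes called were 0 to 1 with either replicate left out, 0 within 25 bp and 0 against windows 500 bp away. 6-mers called numbered 84 within 25 bp, 107 in the 115 stronger peaks, and 102 to 176 with either replicate left out. The E-box difference by signal was 20 percentage points with 100 bp on either side. Beyond fewer peaks or narrower windows, the cause was not tested. Single lists, classes and peaks had 204 such alternatives, of which 43 moved: 8 of the 40 single-replicate ranks of the 20 strongest peaks, which fell beyond the first 20, the lowest at 192 among nuclear peaks of replicate 2, and otherwise list counts of at most 5 genes. Depth was unknown. No paired analysis was possible because there is 1 group.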

Other observations

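The genes and groups in this part were singled out after their values were seen, and the isotype comparison was chosen after the data were seen. Of the 59 nuclear IDR peaks away from the small RNA classes, 3 had a summit in another short structural RNA gene, of kinds that RNA polymerase III transcribes. The gene rpr-1, the RNA of ribonuclease P, lay under the peak at I 13463755 to 13464190 (signal 55.6 ± 26.5, SD, n = 2). The gene mrpr-1 lay under II 7200144 to 7200579 (31.0 ± 4.08, SD, n = 2), and srpr-2.2 under III 5031378 to 5031813 (29.2 ± 7.77, SD, n = 2). By protein-coding genes alone, 35 of these 59 summits were intergenic, 15 intronic, 4 in coding exons, 4 in 3′ UTRs and 1 in a 5′ UTR.

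tRNA genes of different isotypes held an IDR summit at shares from 5.00% (1 of 20 histidine and 1 of 20 methionine genes) to 53.8% (7 of 13 cysteine genes) among isotypes with at least 12 genes. Over 22 groups, 0 differed from the remaining tRNA genes by Fisher's exact test after adjustment. By this exact test, cysteine (unadjusted p = 0.0104, adjusted p = 0.230), alanine (13 of 34, adjusted p = 0.285) and lysine (16 of 46, adjusted p = 0.285) had the lowest values.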
